A study of Homo sapiens with 3 samples.

How the data were processed

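Genomic DNA of 3 MOLM-13 cultures was analysed, 1 per group: a baseline 7 days after infection with the GeCKO v2 library, DMSO, and 50 nM KPT-9274. Per the labels' protocols, cells were infected by lentivirus, selected with puromycin, exposed to drug, and the guide cassette was amplified by PCR from genomic DNA and sequenced. The labels' protocols plan for 76441 guides at 400 cells per guide, whereas the deposited table lists 119461 guides, 63950 of half-library A and 55511 of half-library B; the difference is stated here as found. Per the labels' protocols, the 7 days of puromycin selection were to remove both cells that were not transduced and what is called essential cells there.

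The authors deposited 1 table of normalized counts per guide. MAGeCK is named in the submitters' processing notes, and its version, the trimming, the matching rule and the normalization method are not given in the sources used here. In each library all values were whole multiples of 1 step, so each is a read count divided by 1 size factor, and 100% of the values came out as whole reads within a tolerance of 0.001 reads. The steps gave 30408888, 27235679 and 31370936 reads for baseline, DMSO and KPT-9274. The table's lines mix tabs and spaces, which were both read as separators. Of 18902 names other than microRNAs, 17372 were current symbols in the reference gene table, 1413 older symbols and 117 had no match; the table's names are printed.

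For each comparison a log2 ratio was computed per guide with a pseudocount of 1, so that ratios of low guides are understated. Guides with a mean of at least 20 normalized counts over the 3 libraries were kept (108957 guides), and 20186 names with at least 3 such guides were tested. The ratio was centred and divided by its spread (median absolute deviation) in 50 bins of the mean log2 abundance of the 2 libraries and ranked over all guides. In the setting without a filter, a bin whose guides were at 0 in both libraries took the spread of the nearest bin that had one. Names were tested by alpha-robust rank aggregation, one-sided per direction, counting guides in the extreme 25%. A permutation p came from 2000000 random draws per number of guides and was adjusted by the Benjamini-Hochberg method per direction, with a threshold of 0.05. It treats guides as exchangeable and measures no spread between cultures. Errors beside a name's median are the SD over its guides.

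Gene lists, 31 in number, were fixed beforehand. The median of a list over the medians of its names was placed among 10000 random lists matched on abundance (10 bins) and number of guides. A list below percentile 2.5 or above 97.5 is said to stand apart, as a description of these libraries with no p-value. Named genes followed a rule fixed before the data were examined: HDAC8, SIRT6, NAMPT and PAK4; the 12 names per direction with the smallest rank aggregation score in KPT-9274 against DMSO and the 8 per direction in the other comparisons, among names whose median had that direction (ties by the size of that median, microRNAs counted as genes); of each list described, the 2 lowest and 2 highest members; and any called member of a list. Genes outside it are named in the closing section as chosen after their values were seen. Of the repair lists only some of these members are printed, and some results that the rule names are not reported here.

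The test was tried on simulated data, made by shuffling names over guides and multiplying guides of chosen names by known factors. With no change added it made 0 calls in 6 runs per comparison, where each direction of a shuffle counts as 1 run. In KPT-9274 against DMSO 5.03% of names then had an unadjusted p under 0.05. With changes added, 0.833 unchanged names were called there per simulated data set and direction. Depletions were recovered less often than enrichments. Part of this comes from the ranking. With the centre and the spread taken at the abundance in the reference library, 93.3% of 8-fold depletions were recovered in KPT-9274 against DMSO, against 45.3% as planned. That ranking was therefore added as an alternative after seeing the data, and the planned one was kept as the main result. Lists of 30 random genes moved by 0.25 on the log2 scale stood apart in 67 of 100 cases.

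Alternatives were the pseudocount, the filter, the ranking, the share of guides counted, control guides as the null, the minimum number of guides, leaving out the most extreme guide (of the random draws too), the mean over guides, each half-library alone, the threshold and the scaling. A binomial score of the recovered reads, the ranking by the reference library and the analysis of abundance within libraries were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.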

Results

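A pooled CRISPR knockout screen was read out in MOLM-13, a human acute myeloid leukaemia cell line. Cells carried the GeCKO v2 library, in which each gene is targeted by several guide RNAs, and the abundance of each guide was counted by sequencing the integrated guide cassette. A guide that becomes rarer under a treatment marks a gene whose loss is disadvantageous there. There were 3 libraries and 1 library per group: a baseline taken 7 days after infection, a culture kept in the vehicle DMSO, and a culture kept in 50 nM KPT-9274. This compound is described as an inhibitor of NAMPT, the rate-limiting enzyme of NAD salvage, and of the kinase PAK4. The drug exposure was 5 days, or 3 days if viability went below 20%, and which of these applied is not given in the sources used here. No value below has a replicate check, and every test compares the guides of 2 libraries, not the conditions.

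The baseline library held 30408888 reads, the DMSO library 27235679 and the KPT-9274 library 31370936, with a median of 186, 170 and 195 reads per guide. The table listed 119461 guides, among them 1000 non-targeting controls and 118461 guides for 20697 gene and microRNA names. Guides listed at 0 made up 2.86% of the baseline library (95% Wilson interval 2.76 to 2.95), 3.36% of the DMSO library (3.26 to 3.47) and 3.74% of the KPT-9274 library (3.63 to 3.84). These intervals treat the guides as independent draws and measure no spread between cultures. Reads amplified by PCR are also not independent molecules. The guides at 0 in all 3 libraries numbered 1343, so the zeros were partly shared. The Gini index, which is 0 when all guides are equally abundant, was 0.487, 0.480 and 0.486, and the top 1% of guides held 5.42%, 5.37% and 5.38% of the normalized counts.

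The comparison of KPT-9274 with DMSO asks which gene losses alter the response to the drug, and the series title names HDAC8 and SIRT6. HDAC8, a zinc-dependent histone deacetylase, had a median guide log2 ratio of -0.86 (SD over guides 1.80, 5 guides), and all 5 guides were lower in the KPT-9274 library. SIRT6, an NAD-dependent deacylase that acts in DNA repair, had a median of -0.71 (SD over guides 0.48, 5 guides), again with all 5 guides lower. The HDAC8 value was carried by unequal guides: one had 87.3 normalized counts in DMSO and 2.46 in KPT-9274, a log2 ratio of -4.68, while another stood at -0.15. The SIRT6 guides ranged from -1.48 to -0.26. In the DMSO library gene guides had a median of 133 normalized counts in half-library A and 103 in half-library B. All 5 SIRT6 guides lay above these medians, at 210 to 1241, so their ratios ran opposite to their values in the single library of the denominator. The HDAC8 guides were mixed, with 903 and 458 above and 127, 87.3 and 51.7 below. NAMPT itself had a median of -0.47 (SD over guides 1.08) with 4 of 6 guides lower, and PAK4 had 0.25 (SD over guides 0.35) with 1 of 5 guides lower.

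**Figure D1:**
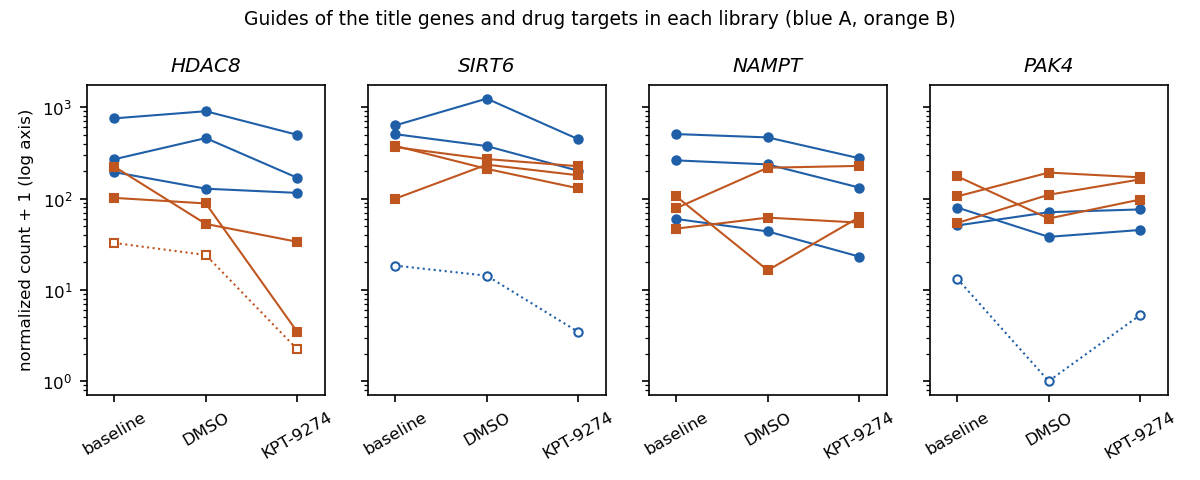
Normalized count plus 1 (log axis) of each guide of HDAC8, SIRT6, NAMPT and PAK4 in the baseline, DMSO and KPT-9274 libraries. Each line is 1 guide, blue circles are half-library A and orange squares half-library B, and open symbols on dotted lines are guides below the abundance filter. All 6 guides of HDAC8 and of SIRT6 lie lower in KPT-9274 than in DMSO.

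Neither title gene passed the test over all genes. SIRT6 had a permutation p of 0.00126 and an adjusted p of 0.681 over 20186 names, and 35 names had a p as small where 25.4 were expected by chance. HDAC8 had a permutation p of 0.00536 and an adjusted p of 0.895, and 121 names had a p as small where 108 were expected. Adjusted over the list alone, which held HDAC8, SIRT6, NAMPT and PAK4, the permutation values were 0.00504 for SIRT6 and 0.0107 for HDAC8. How the study chose HDAC8 and SIRT6 is not given in the sources used here; if it was on these samples, the list values are not independent evidence. With the low guide of each included, all 6 guides of both genes were lower, which was also the case for 273 of 18167 names with 6 guides (1.503%, against 1.56% by chance). In a ranking added after seeing the data, both the centre and the spread of the ratio were taken at the abundance in the DMSO library. The permutation p was then 0.0507 for HDAC8 and 0.205 for SIRT6.

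Across all names, rank aggregation over guides called 0 names depleted and 0 enriched in KPT-9274 against DMSO. At an unadjusted p under 0.05 there were 1012 depleted and 995 enriched names, where chance gives 1009.3. A binomial score of the recovered reads, added after seeing the data, also called 0 in both directions (1020 and 1016 at an unadjusted p under 0.05), as did a test on the mean over guides (1074 and 1014). The smallest scores on the depleted side belonged to PRKAR2B, a regulatory subunit of protein kinase A (median log2 ratio -1.18, SD over guides 1.78), and KLHL2, a ubiquitin ligase adaptor (-1.60, SD 0.99, all 5 guides lower). They were followed by CEP41 (-2.35), SLC20A1 (-0.07), PPEF1 (-0.19), TM6SF2 (-0.20), OR10H4 (-0.94), UHRF1BP1 (-0.33), PRSS42 (-1.09), KCNH2 (-0.52), ZNF454 (-0.95) and C11orf52 (-0.80), and all 12 had an adjusted p of 0.660. OR10H4 is an olfactory receptor. On the enriched side the smallest scores were those of hsa-mir-4269 (median log2 ratio 0.97, SD over guides 1.12, adjusted p 0.262), TXLNG (1.18, all 6 guides higher), RHOXF1 (1.71) and NDUFB2, a subunit of mitochondrial complex I (0.44). OR10K2 (0.76), CTDP1 (2.25), PRSS8 (0.29), CROT (1.84), CXCR3 (1.74), SLC6A12 (1.58), FEV (0.93) and SLC26A5 (1.26) came next, each with an adjusted p of 0.929. The guides of CXCR3, a chemokine receptor, had an SD of 0.32 with all 5 higher, those of FEV, a transcription factor, 0.45 with all 6 higher, and those of CROT, a peroxisomal acyltransferase, 0.63 with all 5 higher.

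Of 31 fixed gene lists, 2 stood apart from random lists in KPT-9274 against DMSO, where 1.55 are expected by chance. The list of the title genes and drug targets had a median log2 ratio of -0.59, at the 0.42 percentile of 10000 random lists, and it contains the 2 genes that the series title names. It stood apart in 6 of 8 alternatives, with medians from -0.85 to -0.16, the latter with half-library B alone, and its bootstrap interval over genes was -0.86 to 0.25. Genes of replication licensing and the replicative polymerases had a median of 0.22 at percentile 98.0, with 24 of 39 tested members higher; MCM6 (1.40) and ORC2 (1.00) were highest, and ORC3 (-1.47) and CDT1 (-0.95) lowest. This list stood apart in only 3 of 8 alternatives (0.07 to 0.31), and its bootstrap interval over genes was -0.06 to 0.38. Its median was -0.13 in DMSO against baseline (percentile 9.76), so the DMSO library that forms the denominator here was itself lower. In KPT-9274 against baseline it was 0.11 (percentile 79.5). Both values lay inside the random range. The routes of NAD salvage had a median of 0.07 (percentile 67.9), with 8 of 20 members lower, from SLC12A8 at -1.18 and NMNAT2 at -0.60 to NMRK1 at 0.39 and NMNAT1 at 0.58. The tryptophan route to NAD had a median of 0.04 (percentile 54.6), and the enzymes that consume NAD one of -0.06 (percentile 20.6), with PARP6 at -0.61 and PARP10 at 1.11.

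Zinc-dependent histone deacetylases had a median of 0.03 (percentile 51.3) over 11 members, with HDAC8 and HDAC2 (-0.30) lowest and HDAC9 (0.62) and HDAC5 (0.48) highest. The 7 sirtuins had a median of -0.05 (percentile 33.9), with SIRT6 and SIRT4 (-0.32) lowest and SIRT1 (0.16) and SIRT5 (0.15) highest. Among DNA repair genes, homologous recombination stood at 0.02 (percentile 50.0), non-homologous end joining at 0.07 (65.5), base excision and single-strand break repair at -0.14 (9.32), mismatch repair at -0.26 (5.11), nucleotide excision repair at -0.09 (17.4), the Fanconi anaemia pathway at -0.20 (4.73) and damage checkpoint signalling at 0.19 (92.0). The lowest repair genes included MAD2L2 (-1.20), CHD1L (-1.18), ERCC1 (-1.06, all 6 guides lower) and XPA (-1.04), and the highest C20orf196 (1.58), DDB1 (1.13) and APEX2 (1.12, all 4 guides higher). None of these genes passed the test over all genes. The means of the NAD salvage (-0.02), mismatch repair (0.01) and Fanconi anaemia (0.01) lists differed in sign from their medians. Apoptosis genes had a median of 0.16 (percentile 92.3) with 21 of 29 higher, and APAF1 (1.41) and BIK (1.21) were highest and BCL2 (-1.40, SD over guides 2.43) and HRK (-0.74) lowest. This list did not stand apart.

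**Figure D2:**
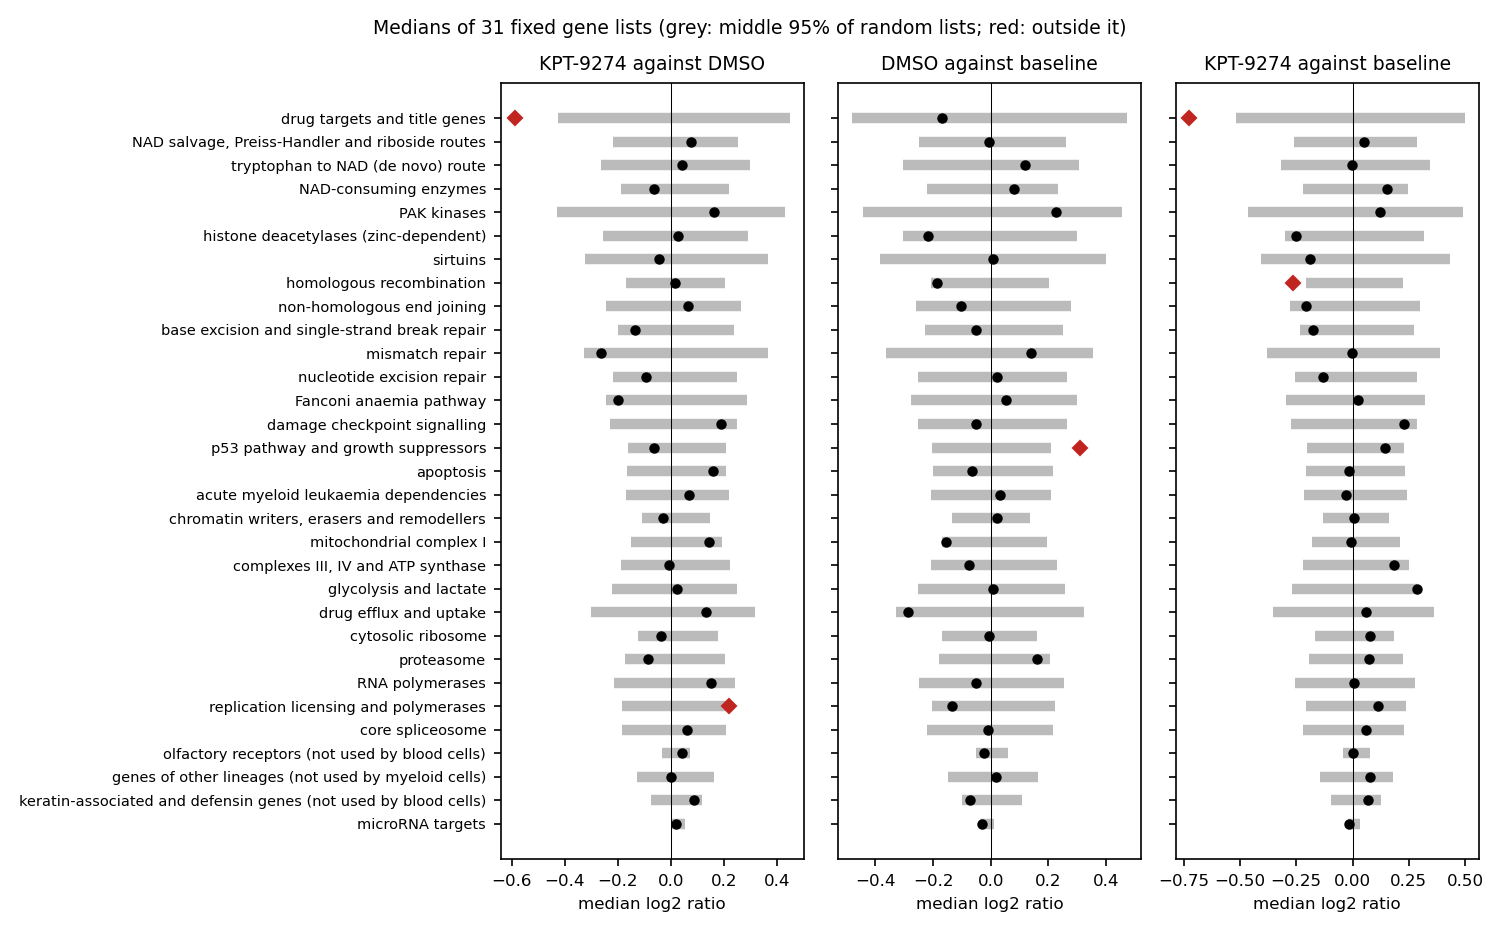
Median log2 ratio of each of 31 fixed gene lists in the 3 comparisons, 1 panel each. Grey bars are the middle 95% of 10000 random lists matched on abundance and number of guides, black circles lie inside them and red diamonds outside: 2 lists in KPT-9274 against DMSO, 1 in DMSO against baseline and 2 in KPT-9274 against baseline.

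The comparison of DMSO with the baseline shows which guides differed after further culture without drug. Of the 31 lists, 1 stood apart, where 1.55 are expected by chance. This list, the p53 pathway and growth suppressors, had a median log2 ratio of 0.31 at percentile 99.9. Higher members numbered 21 of 28 (bootstrap interval of the median over genes 0.20 to 0.53). It stood apart in 6 of 8 alternatives, with medians from 0.17 to 0.35, but in neither half-library alone. In KPT-9274 against the same baseline its median was 0.14 at percentile 87.8, inside the random range. MDM4, an inhibitor of p53, was highest (2.41, SD over guides 1.71, 4 of 5 guides higher), followed by PTPN2, a phosphatase that restrains JAK and STAT signalling (1.49, SD 1.20, all 5 guides higher). Both were among the 4 lowest members in the baseline library that forms the denominator, at -2.73 (MDM4) and -1.66 (PTPN2) relative to the half-library median. CUL3, a ubiquitin ligase scaffold, was among the lower members (-0.61, all 4 guides lower). Over all genes none of these 28 was called, and adjusted over the list alone MDM4 and PTPN2 were.

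Rank aggregation called 0 names depleted and 0 enriched in DMSO against baseline, and 1015 and 1033 names had an unadjusted p under 0.05. The binomial score (1034 and 1005 names under 0.05) and the test on the mean over guides (981 and 1080) also called 0. The smallest depleted scores were those of AVPR1B (median log2 ratio -1.64), SMAD4, which transmits TGF-beta signals (-1.59, SD over guides 0.81, all 6 guides lower), TGIF2, a repressor in the same pathway (-1.28), and hsa-mir-3135a (-2.95), each with an adjusted p of 0.114. C11orf21 (-0.57), WDR46 (-1.11, all 6 guides lower), SON (-0.62) and C11orf63 (-1.92) followed. With guide percentiles taken against the non-targeting controls, 3 of these names passed, namely AVPR1B, SMAD4 and hsa-mir-3135a. Rank aggregation in that setting gave 1964 depleted and 1261 enriched names at an unadjusted p under 0.05, both above the 1009.3 that chance gives. Control guides varied less than gene guides (spread of the log2 ratio 0.637 against 0.956). Those spreads are of ratios not divided by the spread of their abundance bin, whereas the ranked ratios were divided. Whether control and gene guides still differed in spread after the division was not measured, so the cause of the calls was not tested. The smallest enriched scores belonged to UBE4A (1.77, all 5 guides higher), the glycosylase NEIL3 (1.11, all 6 higher), HMGN1 (1.45, all 5 higher), C1orf226 (1.79), KLHL42 (2.02), hsa-mir-557 (1.86, all 3 higher) and CELF6 (0.77), each with an adjusted p of 0.739. The cytosolic ribosome had a median of -0.01 (percentile 50.9) and a mean of -0.14, with 72 of 79 members tested. In the rank aggregation 7 of them had an unadjusted p under 0.05 for depletion and 3 for enrichment. Acute myeloid leukaemia dependencies had a median of 0.03 (percentile 63.8).

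In KPT-9274 against baseline, which shares 1 library with each of the comparisons above and so is not independent of them, 0 names were called in either direction. There were 1071 depleted and 1016 enriched names at an unadjusted p under 0.05, and the binomial score (997 and 989) and the mean over guides (999 and 1019) also gave 0. HDAC8 had a median log2 ratio of -0.76 (SD over guides 1.88, all 5 guides lower, permutation p 0.00216, adjusted p 0.808) and SIRT6 one of -0.69 (SD over guides 0.94, 4 of 5 guides lower, permutation p 0.0198, adjusted p 0.920). In the baseline library SIRT6 stood at 1.85 relative to the half-library median, the highest of the sirtuins. Its ratio thus ran opposite to its value in the single library of the denominator. The smallest depleted scores were those of SLC39A12 (-1.88), MUC5B (-2.27), OR2H1 (-1.93), the ribosomal protein RPL23 (-3.17, all 3 guides lower), CNTN6 (-1.94, all 6 lower), TGIF2 (-1.30), OGFRL1 (-0.65) and RYBP (-0.02). The smallest enriched scores were those of SPIC (1.68, all 5 guides higher), OR4S2 (1.74), GPR25 (1.47), EFHB (2.28), RGS9 (0.84), SPRY2, an inhibitor of receptor tyrosine kinase signalling (1.86), CRISP2 (1.15, all 5 higher) and OTOL1 (2.24).

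Of the 31 lists, 2 stood apart in KPT-9274 against baseline, where 1.55 are expected by chance. The list of title genes and drug targets had a median log2 ratio of -0.72 (percentile 0.37), a bootstrap interval over genes of -0.82 to 0.58, and medians from -0.92 to -0.24 over 8 alternatives, in 6 of which it stood apart. Homologous recombination had a median of -0.27 (percentile 0.52), with 19 of 31 members lower; RAD51D (-1.27) and MRE11A (-1.09, all 6 guides lower) were lowest and MUS81 (1.02) and RMI1 (0.95) highest. In the baseline library, relative to the half-library median, RAD51D (1.05) and MRE11A (1.01) were the 2 highest members and MUS81 (-1.26) and RMI1 (-1.09) among the 4 lowest, so these ratios ran opposite to the values of the single library in their denominator. Its bootstrap interval over genes was -0.57 to 0.05, and it stood apart in 5 of 8 alternatives. Its sign turned with the choice of guides, to 0.07 with a stricter abundance filter and to 0.12 with half-library A alone.

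The guide ratios between separate cultures spread further than counting error alone. Non-targeting guides in KPT-9274 against DMSO had a spread of 0.608 on the log2 scale, 6.21 times the 0.098 that counting their reads gives, and the values were 6.48 and 7.31 times for DMSO and KPT-9274 against baseline. Across 18651 genes, the mean ratios from half-library A and from half-library B, whose guides differ, had a Spearman correlation of -0.010, inside the range of shuffled pairings (-0.014 to 0.014); genes are not independent replicates. In data simulated for KPT-9274 against DMSO with every guide of a gene effective, the test recovered 4% of 2-fold, 18.7% of 4-fold and 45.3% of 8-fold depletions, and 32%, 93.3% and 100% of enrichments of those sizes. With 0.5 of the guides of a gene effective, it recovered 0%, 0% and 5.33% of these depletions and 4%, 48% and 70.7% of the enrichments. The simulated changes were exact factors with no sampling noise added, in names with more kept guides than the minimum. Such rates may overstate recovery from real cultures. The ranking with the centre and the spread taken at the abundance in the DMSO library did better for large depletions. With every guide effective it recovered 2.67%, 40% and 93.3% of depletions of those sizes, and in the real data it also called 0 names depleted. The median guide ratios of HDAC8 and SIRT6 were 1.81-fold and 1.63-fold lower, below the 2-fold size at which few simulated depletions were recovered.

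**Figure D3:**
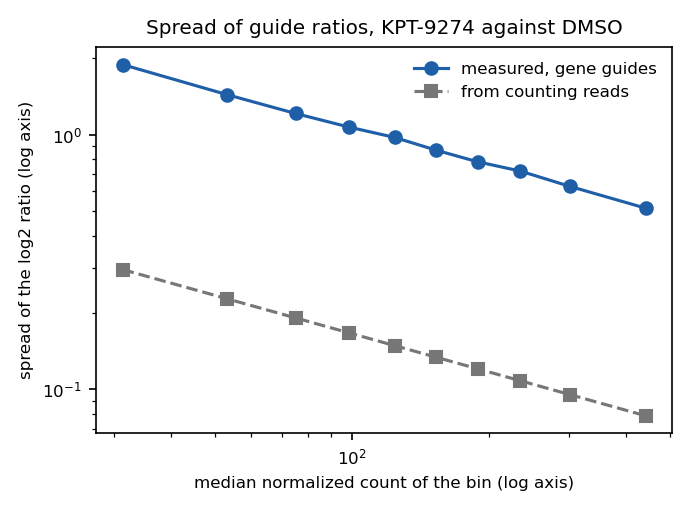
Spread of the guide log2 ratio in KPT-9274 against DMSO (from the median absolute deviation, log axis) in 10 abundance bins of gene guides, against the median normalized count of the bin (log axis). Blue circles are measured values, from 1.89 in the lowest bin to 0.515 in the highest, and grey squares the spread from counting reads alone, from 0.295 to 0.0786.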

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

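The binomial score, the ranking by the reference library, the other rankings of HDAC8 and SIRT6 and the settings of baseline abundance were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of 84 alternatives for the 6 counts of called names, 79 gave 0. The others were 1 enriched name in KPT-9274 against DMSO with half-library B alone (OR10K2), 3 depleted in DMSO against baseline with control guides as the null (AVPR1B, SMAD4, hsa-mir-3135a), 5 there at an adjusted p under 0.25, 1 enriched there with the ratio not divided by its spread (HAUS8), and 1 enriched in KPT-9274 against baseline with no filter (PCNA, most of whose guides are near 0 at baseline). HAUS8 and PCNA were chosen after their values were seen. The cause of these differences was not tested.

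In the 8 alternatives for which their medians were recomputed, HDAC8 (median log2 ratio -2.66 to -0.75) and SIRT6 (-1.19 to -0.39) were lower in KPT-9274 than in DMSO. For the 6 others only the p was recomputed, although leaving out the most extreme guide would also move the median. Over the 13 that gave a p the adjusted p ran from 0.733 to 0.9503 for HDAC8 and from 0.677 to 1.000 for SIRT6. The permutation p ranged from 0.00138 to 0.0507 for HDAC8 and from 0.000623 to 0.462 for SIRT6. SIRT6 was under 0.05 in 9 of 13 alternatives that gave a p and HDAC8 in 12 of 13; HDAC8 in half-library B and SIRT6 in half-library A kept 2 guides, too few for a p. For SIRT6 the exceptions were half-library B alone (0.462), the reference ranking (0.205), the undivided ratio (0.162) and leaving out the most extreme guide (0.0587).

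The number of lists standing apart was 2 in KPT-9274 against DMSO, and 1 with pseudocount 5, with half-library A and with scaling to control guides. In DMSO against baseline it was 1, and 3 with the mean over guides, 4 with half-library A and 2 with half-library B. In KPT-9274 against baseline it was 2, and 1 with the stricter filter, 1 with the mean over guides and 4 with half-library B. A change from 2 to 3 lists was not counted as a change, so settings with 3 lists are not given for the comparisons with 2. Glycolysis and lactate lay just inside the random range in KPT-9274 against baseline (median 0.288, percentile 97.48). The p53 list stood apart in 6 of 8 alternatives, the title list in 6 of 8 and replication in 3 of 8. Of 741 list medians recomputed, 2 changed sign after standing apart: homologous recombination in KPT-9274 against baseline, to 0.069 with the stricter filter and 0.124 with half-library A. The cause was not tested.

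For baseline abundance, 12 lists stood apart, and 7 with half-library B and 7 with the filter of 20. Smaller changes in other settings, if any, are not given. Olfactory receptors turned to -0.073 with the mean over guides, though still above all random lists, and complex I to 0.096 with half-library A, where its median over single guides rather than gene medians kept its sign (-0.0998); the cause was not tested. With the filter of 20, which removes low guides by construction, guides at 0 were 0.225%, 0.379% and 0.404% in baseline, DMSO and KPT-9274, the Gini index 0.445, 0.437 and 0.443, and the top 1% share 5.07%, 5.01% and 5.02%. The top 5% of guides held 18.997%, 18.8% and 18.9%.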

Other observations

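All tests in this part except the test of ribosomal protein paralogs were chosen after the result was seen, and the genes named here after their values were seen. Within the baseline library, each guide was set against the median of its half-library, and the guides of growth genes were already low. The cytosolic ribosome had a median relative log2 abundance of -1.54 (percentile 0 of random lists, 67 of 79 genes below the median), with RPL11 at -5.00 and RPL9 at -4.66. Acute myeloid leukaemia dependencies had -1.29 (percentile 0, 30 of 37 below), among them the phosphatase PTPN11 (-3.98), the Polycomb subunit SUZ12 (-2.74), BCL2 (-2.55) and MYC (-2.35). Replication genes stood at -0.53 (33 of 40 below), with 4 of 6 guides of PCNA and of POLE2 at 0, RNA polymerases at -0.58, the core spliceosome at -0.51, the proteasome at -0.47 and complexes III, IV and ATP synthase at -0.43. The Fanconi anaemia pathway stood at -0.66, checkpoint signalling at -0.51 and complex I at -0.31. Of lists that these cells are not expected to use, olfactory receptors stood at 0.21 (percentile 100), keratin-associated and defensin genes at 0.12 (percentile 93.4) and genes of other lineages at -0.17 (percentile 9.71, 32 of 54 below). Zinc-dependent histone deacetylases stood at 0.57 with all 11 members above the median. The ribosome stood at -1.39 in the DMSO and -1.53 in the KPT-9274 library, and the leukaemia dependencies at -1.08 and -0.92.

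No single gene was called low in the baseline library by rank aggregation (0 of 20398 names, 951 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0612, shared by PCNA, POLE2, H2AFZ and 3 microRNAs. In the same library 11 names were called high.

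The low abundance of growth genes at baseline was weighed against 2 technical explanations. Uneven copy number of single guides in the starting library is argued against for the ribosome list alone. That list stood low with either set of guides, at -1.12 in half-library A and -1.75 in half-library B, and the higher of its percentiles was 0. The other low lists were not put to this test, so it does not decide the question for them. Sequence composition shared by ribosomal protein genes stays open: 7 ribosomal protein paralogs had a median of 0.46, but with an interval of -1.58 to 0.60 that reaches past 0.5 times the list's median (-0.77). A candidate explanation is loss of cells with such knockouts before the baseline was taken; no library from before infection was analysed here, so this is a hypothesis.

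Guide ratios between libraries spread far beyond counting error, and 2 explanations were weighed for KPT-9274 against DMSO. Effects of the targeted genes are argued against as the main source, since half-libraries A and B had a Spearman correlation of -0.010 across genes, inside the shuffled range. The variance fell with abundance with a slope of -0.97 (bootstrap interval -0.99 to -0.95), close to proportion, which is consistent with few independent cells or DNA copies per guide, although counting noise, smaller in size, falls with abundance in the same way. By that reading the spread would equal that of 11.3 molecules per control guide and 5.05 per gene guide. Control guides were 2.13 to 2.23 times as abundant as half-library A gene guides. The protocols planned 400 cells per guide, but for 76441 guides, whereas the table lists 119461. At which step the number was small could not be tested.

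Across the 3 libraries, 7 names were called high in every one, among them CT47A1, GAGE1, PCDHGA1 and UGT1A1, which belong to multigene families. Guide numbers run to 65383 in half-library A and 57028 in half-library B, and 2950 numbers are absent from the table. All 7 names lay above the 95th percentile of absent numbers within 50 positions (median 33.3 against 0.50 over all names), so a candidate explanation is that entries of family members with the same sequence were merged under 1 name. Outgrowth of cells carrying these guides stays open: their median log2 ratio in DMSO against baseline was 0.093 (random lists -0.35 to 0.33), at percentile 71.6, but they were high at baseline already, so outgrowth before it would not show.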
